A study of Mus with 3 samples.

How the data were processed

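The data were 3 one-colour Agilent 4x44K mouse arrays with hippocampal RNA, 1 array for each of the groups NCO, ACO and ASO. Each array held a pool of 10 mice, with 5 sets of 2 mice each, and 200 ng of total RNA was labelled with Cy3, per the labels. All 3 arrays lay on 1 slide, at positions 1, 2 and 4, so slide was no batch between them. Groups were taken from the labels. The labels' protocol names the injected groups as ACO and, in 1 place, with a name that no sample carries; ASO was taken as that group because the design text describes it as injected.

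The foreground and background values are intensities that the authors obtained by scanning at 532 nm on a GenePix 4000B scanner and quantifying spots with GenePix Pro 6.1.0.4, with no normalization, per the file headers. The percent of saturated pixels and the signal to noise score of each spot, with its spot mark, were deposited as GenePix Pro gave them, per the file headers. Agilent Feature Extraction is named in the submitters' processing notes, and the design fixed beforehand assumed its processed signal. The files held GenePix columns instead, so that signal was replaced by limma's normexp correction of the foreground median by the local background median. The authors' deposited value table gives intensities for 475 probes. A straight line of each array's foreground median gave its columns within 0.05, with 44.2, 46.8 and 43.1 subtracted on NCO, ACO and ASO and slopes of 1, 0.917 and 0.893. Its scale is thus linear and its direction that of signal; the reason for the slopes stays unknown.

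Each array had 45220 spots, of which 43020 were gene spots of 39429 probes. Background was corrected with limma 3.58.1 in R 4.3.3 (backgroundCorrect, method normexp, saddle fit, offset 0) on all spots, and control spots were then left out. Each array was scaled to a common 75th percentile, with factors of 1.06 on NCO, 0.949 on ACO and 0.991 on ASO, and 50 was added before log2, which draws the differences of dim probes towards 0. Spots of 1 probe were averaged on the log2 scale. A probe counted as well above background at a signal to noise score of at least 2.6 and as saturated at 50% of saturated pixels, which 3 probes reached on NCO, 5 on ACO and 14 on ASO. It entered a comparison if well above background on both arrays, not saturated on both and without a bad-spot mark, which 2 spots on NCO carried. Later steps ran in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.

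Probes were named through a RefSeq gene table of assembly GRCm38.p6, used for names only: 26581 by accession, 2597 by current symbol, 490 by a synonym and 5 through listed hits. Another 1804 kept the file's name and 7952 had none. A gene was represented by its entered probe with the highest mean over the 3 arrays, and names such as Rpl34-ps1 can stand for near-identical transcripts. Differences of the top and second probe of a gene correlated at r = 0.15 over 3016 genes for ACO against NCO, 0.24 over 3090 genes for ASO against ACO and 0.21 over 3053 genes for ASO against NCO, so different probes often disagreed. Some genes at least 2-fold apart had a second probe. It went the same way in 1 of 1 higher gene for ACO against NCO. For ASO against ACO it did so in 0 of 1 higher and 2 of 3 lower genes, and for ASO against NCO in 0 of 2 and 1 of 2.

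With 1 array per group no test was run and no p-value is given. Genes were counted by a size rule of 2-fold. Before the data were examined, 38 gene lists for cell types, neighbouring regions and pathways were fixed. A list with at least 4 measured genes was described by its median difference and its percentile among 10000 random lists of the same size drawn within 20 bins of mean signal, and was called apart outside the middle 95%. The random lists draw genes independently, while genes of 1 cell type or pathway can move together. A call therefore describes these arrays and gives no rate of false calls. The other-tissue and other-region lists cover choroid plexus, leptomeninges, ependyma, blood, endothelium, striatum, thalamus and habenula, and hypothalamus and pituitary. The brain cell lists cover homeostatic and disease-associated microglia, astrocytes, reactive astrocytes, oligodendrocytes, their precursors, dentate granule cells, CA1 and CA3 pyramidal cells, interneurons and adult neurogenesis. The pathway lists cover immediate early genes, cytokines and NF-kB targets, interferon response, complement and MHC, NRF2, unfolded protein response, heat shock, amyloid and tau processing, the cholinergic system, glutamate receptors, synaptic vesicles, neurotrophins, glucocorticoid targets, PPAR targets, cholesterol biosynthesis, oxidative phosphorylation, ribosomal proteins, apoptosis and the circadian clock.

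Named genes were fixed by a rule: the 10 highest and 10 lowest differences in ACO against NCO and in ASO against ACO, and the 5 highest and 5 lowest in ASO against NCO. They had a mean signal at or above the lower quartile of entered genes, a name that is not a predicted or clone name, and no other entered probe in the opposite direction. The rule added the 3 largest bounds each way, up to 5 genes at least 2-fold apart in opposite directions, every list member at least 2-fold apart and the 2 to 4 members of a list with the largest differences; some members are not reported here. A gene not well above background on 1 of the 2 arrays was given as at least N-fold, from the bright array's level over the higher of the dim array's own level and the lowest level there of any probe well above background; bounds were not corrected for the signal of the surrounding spots.

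The steps were tested on simulated data with the measured spot error, 5 simulations per comparison with 200 changed genes each. For ACO against NCO (13317 genes) the 2-fold rule recovered 81.3% of genes changed 2.5-fold and 92.2% of those changed 3-fold, for ASO against ACO (13570 genes) 77.3% and 91.9%, and for ASO against NCO (13459 genes) 79.7% and 93.2%. It recovered 0% of genes changed 1.5-fold in each, and called 0 unchanged genes. Both results were fixed in advance by the small simulated error, which was independent between spots. Dark areas, faulty probes and differences between pools were not simulated, so these simulations do not give the rate of false 2-fold calls in the real data. Lists with no change stood outside the middle 95% in 3.24% of 185 lists for ACO against NCO (13317 genes), 4.21% of 190 for ASO against ACO (13570 genes) and 2.16% of 185 for ASO against NCO (13459 genes). In each comparison 5 of 5 lists of 15 genes shifted by 0.4 were called. The simulated error was independent between genes, so these rates do not hold for lists whose genes move together.

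Alternatives fixed beforehand were median scaling, quantile and cyclic loess normalization, normexp on spot means (run as above, with offset 0 and 50 added after scaling, in place of the offset of 50 fixed for it), no filter or a stricter filter on dim probes, the mean over a gene's probes, marked spots kept, size rules of 1.5-fold and 3-fold, list means, unmatched random lists, the upper part of genes by signal, and the authors' value table. Added after the data were seen were a correction of each spot by the spots around it (5 by 5 positions), no added constant, a threshold from negative control spots, and leaving out the largest dark area of the ASO array.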

Results

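Gene expression was measured in the hippocampus of male Slc:ddY mice, an outbred stock, in 3 groups of 10 mice aged 6 weeks. For 15 days the normal control group (NCO) and the peptide control group (ACO) received distilled water by mouth, and the oil group (ASO) received 2000 mg/kg/day of shochu oil, the oily fraction of a spirit distilled from sweet potato. On day 8 each mouse received 5 µL of fluid, which was distilled water in NCO and a solution with 10 nmol of Aβ25-35 in the cerebral ventricles of ACO and ASO. The labels do not spell out the route of the water in NCO. If it was not given into the ventricles, effects of the injection itself cannot be told apart from those of the peptide. Aβ25-35 is a short, toxic fragment of the amyloid β peptide. The hippocampus was collected after a Y-maze test of short-term memory on day 16. RNA of 2 mice made 1 set, the 5 sets of a group were pooled in equal amounts, and each pool was labelled with Cy3 and hybridised to 1 array. There were therefore 3 arrays and no replicates, and their number limits the precision of every value.

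Of 39429 gene probes, 20071 (50.9%) were well above background on the NCO array, 20371 (51.7%) on the ACO array and 21185 (53.7%) on the ASO array. The median foreground intensity was 88 on NCO, 95 on ACO and 97 on ASO, against a median local background of 44, 44 and 43. Across 21226 spots, log2 signals correlated at r = 0.997 between ACO and NCO, 0.993 between ASO and NCO and 0.993 between ASO and ACO. Among probes printed at 10 spots, the median SD of the difference between 2 arrays over the spots was 0.08 for ACO against NCO, 0.09 for ASO against ACO and 0.10 for ASO against NCO. This SD holds spot error only, and no test between groups was possible with 1 pool each. All differences below are log2 values of the first named array minus the second, and percentiles describe these arrays.

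The comparison of ACO with NCO asked what the injected peptide did in the hippocampus, within the limit that the route in NCO is not known. Genes of the interferon response, of complement and antigen presentation and of choroid plexus epithelium were higher on the ACO array, and genes of myelin and of cholesterol synthesis were lower. All 9 measured interferon response genes were higher, with a median difference of 0.27, led by Ifi27l2a at 0.81 and Bst2, an antiviral tethering protein, at 0.73. C4b, a component of the classical complement pathway, differed by 0.93, and 16 of 17 measured choroid plexus genes were higher with a median of 0.37. All 13 measured oligodendrocyte and myelin genes were lower, with a median of -0.13.

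Of 37 lists with at least 4 measured genes, 6 stood above and 5 below the middle 95% of 10000 random lists matched on signal. Lists of independent genes would put 1.85 outside it, but genes of 1 list can move together. The interferon list stood at percentile 100, and so did the complement and MHC list, whose median was 0.19 with 8 of 12 genes higher. In that list H2-Eb1, an MHC class II chain, differed by 0.62, while the 3 genes of the C1q complex were lower, C1qb at -0.56, C1qc at -0.45 and C1qa at -0.26. Reactive astrocyte genes had a median of 0.17 (percentile 100), with 16 of 21 higher, among them Emp1 at 0.36, Vim and Gbp2 at 0.30, and with Cd44 at -0.30. Only 4 of 18 cytokine and NF-kB target genes were measured on both arrays. All 4 were higher, with a median of 0.21 (percentile 99.6), from Cxcl10 at 0.26, Ptgs2 at 0.23 and Tlr2 at 0.20 to Nfkbia at 0.02, but over all 18 members, with no filter on dim probes, the median was 0.019 (percentile 84.2).

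Choroid plexus epithelium is a neighbouring tissue that secretes cerebrospinal fluid, and its list stood at percentile 100. Kcne2 differed by 0.61, Slc4a5 by 0.60, Calml4 by 0.59 and the transcription factor gene Otx2 by 0.56. Ttr, which encodes transthyretin and was among the brightest members, was the 1 gene on the other side, at -0.46. All 6 measured thalamus and habenula genes were higher as well, with a median of 0.16 (percentile 99.6) and Tnnt1 at 0.56, but a median of 0.045 (percentile 86.2) over 11 genes with no filter on dim probes and 0.093 (percentile 94.8) with the mean over a gene's probes.

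Among the lower lists, oligodendrocyte and myelin genes stood at percentile 0.03, with Cnp at -0.31, Mog at -0.23 and Aspa at -0.22. Cholesterol biosynthesis genes had a median of -0.11 (percentile 0.06) with 16 of 18 lower, including Insig1 at -0.29 and Stard4 at -0.28. CA1 pyramidal cell genes had a median of -0.11 (percentile 1.5) with 4 of 6 lower, Fibcd1 at -0.23 and Wfs1 at -0.14; the call ended under 5 alternatives, with a median of -0.048 (percentile 23.6) when spot means replaced medians. Genes of glutamate receptors and the postsynapse had a median of -0.06 (percentile 1.63) with 12 of 17 lower, and Gria1, an AMPA receptor subunit, was at -0.56, but quantile normalization gave a median of -0.040 at percentile 6.49. Endothelial genes had a median of -0.10 (percentile 0.9) with 9 of 11 lower, Kdr at -0.18 and Esam at -0.17, but after correction for signal across the array surface their median was -0.03 at percentile 17.0. Homeostatic microglia genes (median -0.06, percentile 2.62) and disease-associated microglia genes (0.04, percentile 92.9) lay inside the middle 95% of random lists, though by list means they lay outside it, at -0.13 and 0.08.

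By single genes, 5 of 13317 were at least 2-fold higher on ACO and 5 at least 2-fold lower, and 94.5% lay within 1.2-fold. The highest by the fixed rule were Trip10 at 1.17, Pink1, a kinase of mitochondrial quality control, at 1.10, C4b, Ifi27l2a, Plxna4, a semaphorin co-receptor, at 0.75, Bst2, Mcee at 0.65, the interferon-induced GTPase gene Tgtp2 at 0.64, Camk2n1, an inhibitor of CaMKII, at 0.64 and Cwc22 at 0.63. The lowest were Pinx1, a telomerase inhibitor, at -1.62, Itgam, the CD11b integrin of microglia, at -1.17, Zfp442 at -0.88, Spout1 at -0.82, the peptide amidating enzyme gene Pam at -0.82, the mitochondrial channel gene Vdac2 at -0.72, Dpysl3 at -0.68, Abhd1 at -0.67, Tbc1d30 at -0.65 and Chst11 at -0.64. Signal of Pinx1 was 454 on ACO and 1500 on NCO, and that of Itgam 3760 and 8521, and Itgam was at -0.94 after correction by the surrounding spots. The counts also held genes outside the rule, named after their values were seen: Lemd3 at 1.82, Klk6 at 1.16 and Pold1 at 1.02 were higher, and Lyz1 at -1.43, Gm3893 at -1.32 and LOC100503421 at -1.05 were lower. A second Lemd3 probe stood at 0.05. The spots around Lemd3 and Pold1 stood at -0.34 and -0.31, and 17 of 13317 genes had surroundings at least 0.3 from 0. After correction by those spots Lemd3 was at 2.17 and Pold1 at 1.33.

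Some genes were not well above background on 1 of the 2 arrays and have bounds only. Ifi214, an interferon-inducible gene, was at least 29.9-fold higher on ACO, F5 at least 1.66-fold and Rev1 at least 1.49-fold higher, while Cstdc2 was at least 14.9-fold, Ms4a19 at least 1.66-fold and Pde5a at least 1.52-fold lower. The counts depended on the processing, with 3 genes at least 2-fold higher, 1 of them shared, when spot means replaced medians. Of the 10 genes at least 2-fold apart, 4 of the 5 higher and all 5 lower rested on 1 measured probe.

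**Figure D1:**
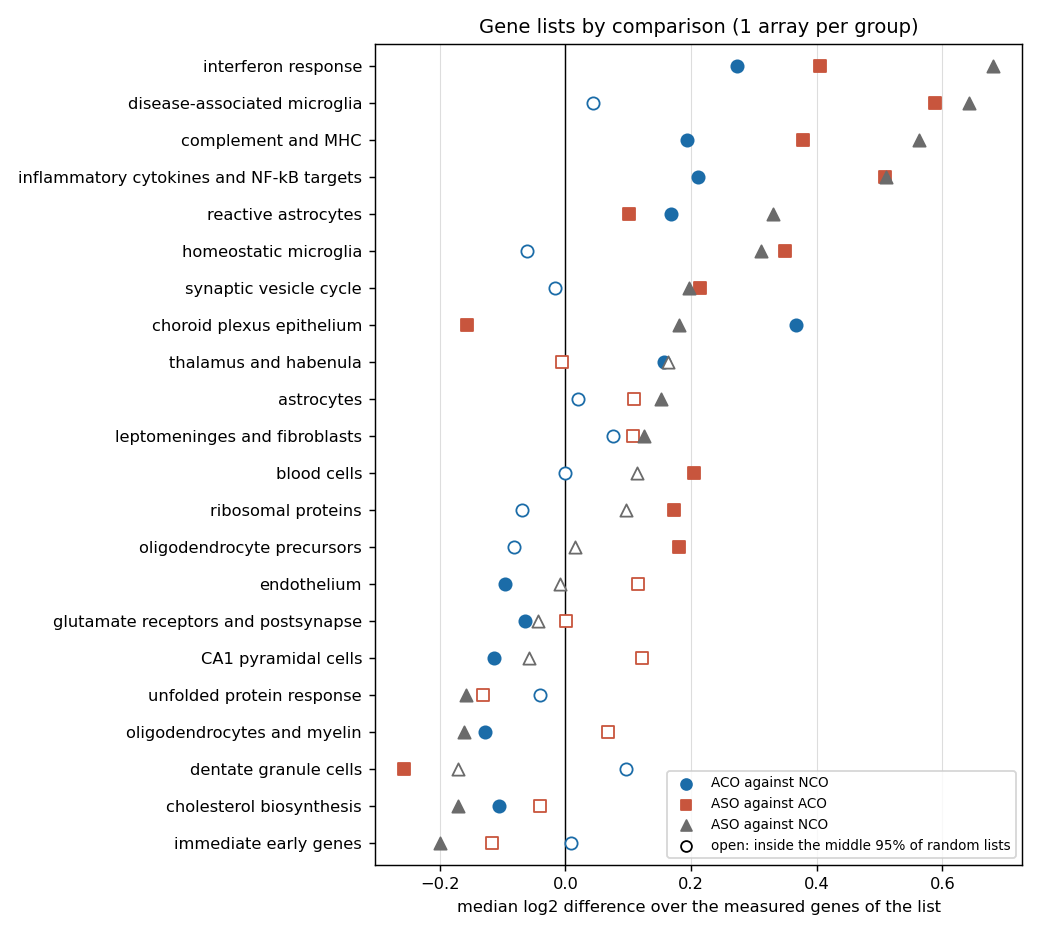
Median log2 difference (horizontal axis) of the 22 gene lists that stood outside the middle 95% of matched random lists in some comparison, 1 symbol per comparison, with open symbols inside the middle 95%. The interferon list lies at 0.27 for ACO against NCO and 0.68 for ASO against NCO, and the disease-associated microglia list at 0.04 and 0.64.

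The comparison of ASO with ACO asked what the oil did in peptide-injected mice. Microglial, complement and interferon genes were higher on the ASO array. Of the disease-associated microglia genes, which phagocytic microglia switch on, 14 of 15 were higher with a median of 0.59, including Cst7 at 1.47, Cd52 at 1.24 and Gpnmb at 1.01. The 3 genes of C1q, the recognition molecule of the classical complement pathway, were each at least 2-fold higher, C1qb at 1.19, C1qc at 1.08 and C1qa at 1.02. C1qa was at 0.84 after correction by the surrounding spots. The C1q genes were lower on ACO than on NCO, and they were not at least 2-fold higher on ASO than on NCO. All 10 measured genes of dentate granule cells were lower, with a median of -0.26.

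Of 38 lists tested, 10 stood above and 2 below the middle 95% of random lists, where lists of independent genes would give 1.9. Disease-associated microglia, homeostatic microglia, interferon response and complement and MHC genes each stood at percentile 100. Homeostatic microglia genes had a median of 0.35 with 13 of 14 higher, and 3 of these 14, the C1q genes, also belong to the complement list. Trem2 differed by 0.91 and Tyrobp, its signalling adaptor, by 0.81, while P2ry12, a purine receptor of resting microglia, was at -0.40. Itgax was at 0.86, the C-type lectin gene Clec7a at 0.82 and Spp1 at 0.71. Of the 3 disease-associated microglia genes with over 1 measured probe, Ctsd had its probes on the same side, at 0.45 and 0.60, while those of Lpl ranged from -0.24 to 0.12 and those of Csf1 from -0.09 to 0.05. Interferon response genes had a median of 0.40 with 8 of 9 higher, from Ifi27l2a at 0.85, Oas1a at 0.77 and Ifit3 at 0.57 to Bst2 at -0.05. Complement and MHC genes had a median of 0.38 with 10 of 12 higher, among them Cd74, the MHC class II invariant chain, at 0.64 and C3 at 0.58, and with H2-Eb1 at -0.73.

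Reactive astrocyte genes had a median of 0.10 (percentile 98.7) with 19 of 22 higher (percentile 96.8 under a stricter filter on dim probes), led by Lcn2 at 1.05, Cxcl10 at 1.00, Timp1 at 0.85 and Gfap, the astrocyte intermediate filament, at 0.84. Of the cytokine and NF-kB target genes 5 of 18 were measured, with a median of 0.51 (percentile 99.98), the chemokine gene Ccl3 at 1.18, Tlr2 at 0.51 and Ptgs2 at -0.50. Synaptic vesicle genes had a median of 0.21 (percentile 99.9) with 11 of 16 higher, including the calcium sensor gene Syt1 at 0.63, Cplx2 at 0.62 and Rab3a at 0.50. Oligodendrocyte precursor genes had a median of 0.18 (percentile 99.4) with 6 of 9 higher and Cspg4 at 0.42, but a median of -0.00054 under a stricter filter on dim probes. Ribosomal protein genes had a median of 0.17 (percentile 97.7) with 19 of 22 higher and Rpl37 at 0.53; quantile normalization brought this median to 0.0061.

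Blood cell genes stood apart with these lists, at a median of 0.21 (percentile 99) with 7 of 8 higher, the globin gene Hbb-b2 at 0.93 and the neutrophil gene S100a9 at -0.68, but at 0.11 with quantile normalization (percentile 96.6) and with no filter on dim probes (percentile 94.9). Spike-in control transcripts were also brighter on ASO, with a median difference of 0.66 over 5 control probes, which is larger than the medians of the 4 microglial, interferon and complement lists, and the labels do not say whether each reaction received the same amount. Among the lower lists, dentate granule cell genes stood at percentile 0.06, with the calcium buffer gene Calb1 at -0.49, Trpc6 at -0.37 and C1ql2 at -0.32. Choroid plexus genes had a median of -0.16 (percentile 0.34) with 13 of 18 lower, Kcne2 at -0.56 and Otx2 at -0.38. Immediate early genes, which report recent neuronal activity, had a median of -0.12 and lay inside the middle 95% (percentile 3.28), with Egr2 at -0.51, Egr1 at -0.45 and Fos at -0.42. They lay outside it under 5 alternatives, at -0.19 (percentile 0.15) after correction by the surrounding spots and -0.22 (percentile 0.14) under a stricter filter on dim probes.

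Of 13570 genes, 25 were at least 2-fold higher on ASO and 9 at least 2-fold lower. Of the 25, 24 rested on 1 measured probe, and the second probe of the other, Idua, stood at -0.0026. With spot means 16 of the 25 were still at least 2-fold higher, and after correction by the surrounding spots 17 were, without C1qa, Lcn2 (0.91), Fgf23 (0.86), Ccl3 (0.85), Lepr (0.79), Idua, Gm6919 and Gm6272. Among the genes higher on ASO, 8 belong to 6 lists of microglia, astrocyte reaction, complement, interferon and cytokine genes, and another 8 carry predicted or clone names. The highest by the fixed rule were Rpl34-ps1 at 1.41, Cd52 with a signal of 645 against 244, C1qb with 1271 against 530, the phosphatase gene Ppp5c at 1.10, the hormone gene Fgf23 at 1.09, C1qc, the leptin receptor gene Lepr at 1.08, Pinx1 at 1.07, C1qa and Tex44 at 0.98. C1qc was printed at 10 spots, whose differences had an SD of 0.07. Among genes outside the rule, the chemokine gene Ccl5 at 1.04 and the inhibitory receptor gene Lilrb4a at 1.18 were chosen after their values were seen.

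The lowest were Ccdc59 at -1.84, Fra10ac1 at -1.50, Ppp2r2c, a regulatory subunit of phosphatase 2A, at -1.46, Pdp1 at -1.46, Degs1, a ceramide synthesis enzyme, at -1.28, Sh3bgr at -1.25, Abcb9 at -1.20, the kinesin light chain gene Klc1 at -1.04, Ktn1, with a signal of 819 against 1684, and Sfr1 at -0.99. Signals are printed without the added constant, and with it Ktn1 fell short of 2-fold. Sort1, outside the rule, was at -1.27 with a second probe at 0.10. Abcb9, Ccdc59, Degs1, Fra10ac1, Klc1, Pdp1 and Sort1, 7 of the 9 genes at least 2-fold lower, had their spots in 1 dark area of the ASO array that covered 0.372% of its positions and held 37 of the 13570 genes. Without that area 2 genes were at least 2-fold lower, Ppp2r2c and Sh3bgr, and both Sh3bgr probes were low, at -1.25 and -1.11. The largest bright area of the ACO array lay within the bounds of this dark area. Its median was 0.27 above the mean of the other 2 arrays. That mean includes the dark ASO array, so the overlap is partly built in and is no separate evidence of a bright area on ACO. The 7 genes of the dark area were also at least 2-fold lower on ASO than on NCO. Among genes with bounds, Cstdc2 was at least 10.2-fold, A3galt2 at least 4.45-fold and Tnp1 at least 2.18-fold higher on ASO, and Ifi214 was at least 27.8-fold, Dach2 at least 1.37-fold and Dnal1 at least 1.34-fold lower.

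**Figure D2:**
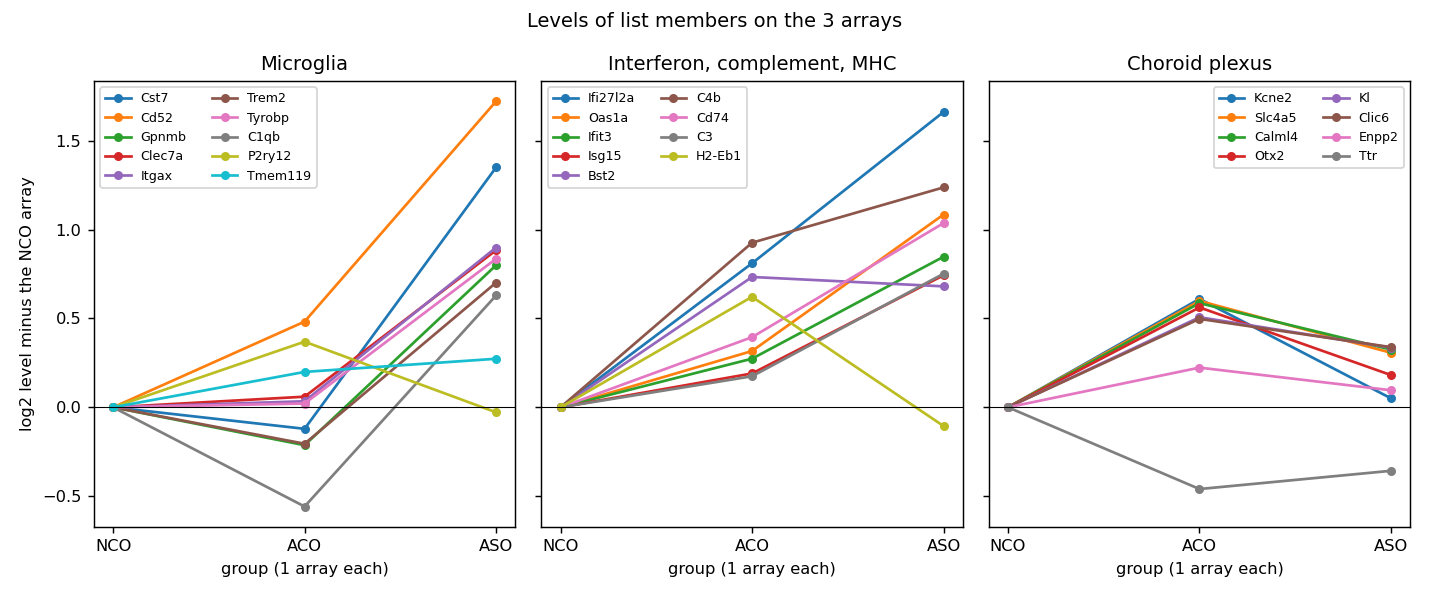
Log2 level of list members on the 3 arrays relative to the NCO array (vertical axis), for microglial genes, for interferon, complement and MHC genes, and for choroid plexus genes; each point is 1 array. Cd52 stands at 0.48 on ACO and 1.72 on ASO, and Kcne2 at 0.61 on ACO and 0.05 on ASO.

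**Figure D3:**
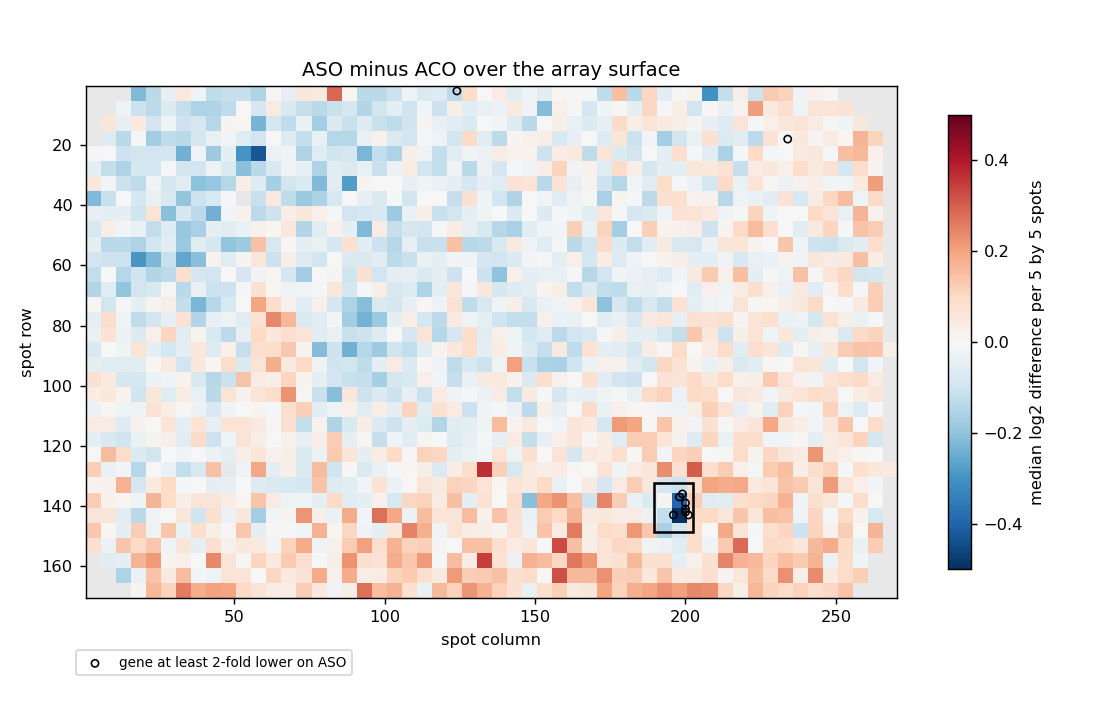
Median log2 difference of ASO minus ACO per block of 5 by 5 spots over the array surface, with spot columns and spot positions down the array as axes, and circles at the 9 genes at least 2-fold lower on ASO. Colours end at the limits of the scale; the lowest block was at -0.77, inside the boxed area, where 7 of the 9 circles lie.

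The comparison of ASO with NCO asked how far the oil-treated, peptide-injected mice stood from normal controls. Interferon, microglial and complement genes were higher on ASO than on NCO. All 9 measured interferon response genes were higher, with a median of 0.68, including Ifi27l2a at 1.66, Oas1a at 1.08 and Ifit3 at 0.85. Disease-associated microglia genes had a median of 0.64 with 14 of 15 higher, including Cd52 at 1.72, Cst7 at 1.35 and Ccl6 at 1.19. Complement and MHC genes had a median of 0.56 with 10 of 12 higher, including C4b at 1.24 and Cd74 at 1.04. Spike-in control transcripts were also brighter on ASO than on NCO, with a median difference of 0.46 over 5 control probes.

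Of 37 lists tested, 10 stood above and 4 below the middle 95% of random lists, where lists of independent genes would give 1.85. Homeostatic microglia genes had a median of 0.31 with 12 of 14 higher, Tyrobp at 0.84, Aif1 at 0.82 and Itgam at -0.82; this list and the 3 above stood at percentile 100. Reactive astrocyte genes were at 0.33 (percentile 100), with Lcn2 at 1.32, Cxcl10 at 1.26, Vim at 0.87 and Gfap at 0.84, and astrocyte genes at 0.15 (percentile 99.6), with Gjb6 at 0.54 (percentile 96.7 with the mean over a gene's probes). Cytokine and NF-kB target genes were at 0.51 (percentile 99.96, 4 genes), and synaptic vesicle genes at 0.20 (percentile 99.98), with Rab3a at 0.71 and Syn1 at 0.62. Choroid plexus genes were at 0.18 (percentile 99.9), with Sostdc1 at 0.47 and Ttr at -0.36, and leptomeningeal and fibroblast genes at 0.12 (percentile 97.9), with Col1a1 at 0.57 (percentile 95.8 under a stricter filter on dim probes). Immediate early genes were lower, at -0.20 (percentile 0.04), with Egr1 at -0.48 and Nr4a1 at -0.44, and so were cholesterol biosynthesis genes, at -0.17 (percentile 0.12), with Idi1 and Sc5d at -0.51. Unfolded protein response genes were at -0.16 (percentile 1.57), with Xbp1 at -0.29 and Hspa5 at -0.27, and oligodendrocyte and myelin genes at -0.16 (percentile 1.74), with Aspa at -0.33 and Mag at 0.34, but at -0.10 (percentile 8.91) when spot means replaced medians and -0.082 (percentile 10.8) by the list mean.

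Of 13459 genes, 24 were at least 2-fold higher on ASO than on NCO and 12 at least 2-fold lower. Of the 24, 22 rested on 1 measured probe, and for the other 2 the second probe did not differ in the same direction. With spot means 15 of the 24 were still at least 2-fold higher, and after correction by the surrounding spots 20 of the 24 and 8 of the 12 lower genes were past 2-fold. The highest by the rule were Cd52, Ifi27l2a, Mpeg1, a macrophage pore-forming protein, at 1.39, Fgf23 at 1.38 and Rpl34-ps1 at 1.31. The lowest were Ccdc59 at -1.80, Fra10ac1 at -1.47, Pdp1 at -1.40, Ppp2r2c at -1.39 and Abcb9 at -1.34. Without the dark area 5 genes were at least 2-fold lower. By bounds, A3galt2 was at least 3.76-fold and the chemokine genes Ccl3 and Ccl4 at least 2.31-fold and 2.27-fold higher on ASO, and Scyl3 was at least 1.65-fold, Has2os at least 1.34-fold and Dnal1 at least 1.33-fold lower. These bounds were not corrected for local signal, and the spots around Scyl3 stood at -0.38 and those around Ccl3 at 0.43.

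Of the 38 lists, 16 lay inside the middle 95% of random lists in each comparison that tested them, but 7 of these left it under some alternative; their medians follow for ACO against NCO and then for ASO against ACO. Genes of amyloid and tau processing were at 0.01 and 0.03, with Clu at 0.55 on ASO against ACO, and cholinergic genes at -0.04 and -0.01, with the acetylcholinesterase gene Ache at 0.21 on ASO against ACO. Neurotrophins and growth factors were at 0.06 and -0.03, with Bdnf at -0.41 and Vgf at 0.52 on ASO against ACO. NRF2 and antioxidant genes were at -0.05 and 0.06, and PPAR target and fatty acid oxidation genes at 0.06 and -0.13 (percentile 3.06). Glucocorticoid targets were at 0.04 and -0.04, heat shock genes at -0.05 and 0.01, apoptosis genes at 0.06 and -0.04, circadian clock genes at -0.03 and 0.08, and oxidative phosphorylation genes at -0.08 and 0.13. Among cell type lists, CA3 pyramidal cell genes were at -0.09 and 0.08, interneuron genes at 0.01 and 0.0021, adult neurogenesis genes at 0.04 and -0.03, ependymal genes at 0.08 and -0.06, and striatal neuron genes at 0.04 and 0.0028. Hypothalamic and pituitary genes were at 0.02 (3 genes, not ranked) and 0.12. For ACO against NCO, the lists that left the middle 95% were ependyma under 8 alternatives (up to 0.17), oxidative phosphorylation under 4, CA3 cells and glucocorticoid targets under 2 each and apoptosis under 1. For ASO against ACO they were oxidative phosphorylation under 6 alternatives, PPAR targets under 3 and NRF2 under 1 (0.13), and for ASO against NCO PPAR targets under 3 and NRF2 under 1 (0.11).

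The differences of ACO minus NCO and of ASO minus ACO correlated at r = -0.30 across 13189 genes, which are not independent replicates. The 2 differences share the ACO array, and simulated unchanged arrays with spot error alone gave r = -0.50. Their covariance was -0.0095 against a simulated -0.0044; the pair that shares NCO had -0.0101 and the pair that shares ASO -0.0407. Of 13195 genes measured in both comparisons, Pinx1 was at least 2-fold one way and then the other, at -1.62 and 1.07. By bounds, Ifi214 was at least 29.9-fold higher on ACO than NCO and at least 27.8-fold lower on ASO than ACO, and Cstdc2 at least 14.9-fold lower and then at least 10.2-fold higher. At 1.5-fold, 7 of the 13195 genes were lower on ACO than NCO and higher on ASO than ACO, namely Fggy, LOC790956, Lbhd2, Lyz1, Pinx1, Spout1 and Vdac2. Another 5 genes, H2-Eb1, Pink1, S100a9, Sh3bgr and Tgtp2, were higher and then lower. A high or low ACO value alone gives opposite differences, and the number of such genes that unchanged groups would give was not computed.

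**Figure D4:**
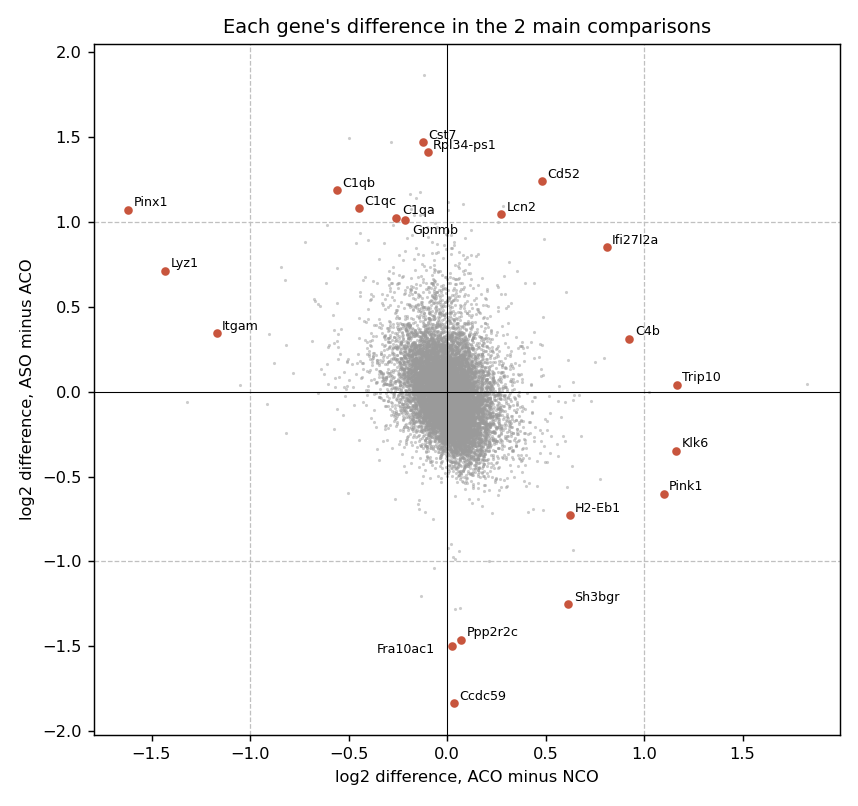
Each gene's log2 difference of ACO minus NCO (horizontal axis) and of ASO minus ACO (vertical axis), 1 point per gene measured in both comparisons with selected genes in red, and broken lines at 2-fold; genes with bounds, such as Ifi214 and Cstdc2, are not plotted. Among the plotted genes Pinx1 lies past the lines in opposite directions, and C1qb, C1qc and C1qa lie at 1.02 or above on the vertical axis.

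The authors' deposited value table held 475 probes, and each column followed that array's foreground median minus a constant, times a constant. Its column medians were 117 on NCO, 97.4 on ACO and 113 on ASO. Every probe had a ratio of ACO over NCO of at least 1.51 or at most 0.755 in that table, 144 above 1 and 331 below, so the probes were chosen on these samples. In it 355 probes (74.7%) differed the other way in ASO against ACO, which is no independent evidence of a return towards NCO, since a high or low ACO value enters both differences.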

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

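The spike-in comparison was chosen after its values were seen. Control spots for spike-in transcripts, which none of the comparisons above use, were brighter on the ASO array: the median log2 difference over 5 probes well above background was 0.66 against ACO (0.41 to 0.84) and 0.46 against NCO (0.26 to 0.69), while ACO against NCO gave -0.16 (-0.19 to -0.12). The labels do not say whether the same amount was added to each labelling reaction, and no explanation was tested. If the same amount was added, differences of ASO minus ACO relative to these spots would be lower by about 0.66 than those reported, which are relative to the 75th percentile of each array, and the medians of 0.59, 0.40, 0.38 and 0.35 for disease-associated microglia, interferon, complement and homeostatic microglia genes would lie near or below 0. Likewise, differences of ACO minus NCO would be higher by about 0.16. The medians of the 5 lower lists, from -0.13 to -0.06, would then lie above 0. Those of ASO minus NCO would be lower by about 0.46, which would put homeostatic microglia genes (0.31) below 0. Interferon (0.68), disease-associated microglia (0.64) and complement genes (0.56) would stay above 0. A common shift of this kind would move all genes alike, so the place of these lists among random lists would stay about the same.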

How the results depend on the processing

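The alternatives with spatial correction, no constant, a negative-control threshold or the dark area left out were chosen after seeing the data. No paired analysis was possible because each group had 1 array; for the same reason no replicate could be left out. Counts from the authors' value table were not run, since its 475 probes were selected on the ratio of ACO to NCO. Signal over background limits the values: only 20071 to 21185 of the 39429 probes per array were well above background, and the added constant shrinks differences of dim probes. Scaling moved the median of all genes to -0.034 at the farthest, and the correlation of the differences stayed between -0.374 and -0.295. Of 5771 values of named genes pooled over the alternatives, 5309 moved by less than the spot error and 462 moved further. No filter, the stricter filter, the negative-control threshold and marked spots kept only change which probes or spots enter. Under each of these, 0 values moved further. Further moves were 135 of 485 with normexp on spot means, 132 of 485 with spatial correction and 41 of 66 with the authors' values. Of values at least 2-fold apart, 0 changed sign, and this count is not given for smaller values.

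For ACO against NCO, the 5 genes at least 2-fold higher became 3 with normexp on spot means, 2 with the stricter filter, 27 at 1.5-fold and 1 at 3-fold; the 5 lower became 3 with the stricter filter, 9 with no constant, 28 at 1.5-fold and 1 at 3-fold. For ASO against ACO, the 25 higher became 46 with no constant, 222 at 1.5-fold and 1 at 3-fold; the 9 lower became 14 with no constant, 2 without the dark area, 37 at 1.5-fold and 1 at 3-fold. For ASO against NCO, the 24 higher became 14 with the stricter filter, 52 with no constant, 222 at 1.5-fold and 4 at 3-fold; the 12 lower became 5 without the dark area, 48 at 1.5-fold and 1 at 3-fold. A stricter filter tests fewer genes and another size rule moves the limit; the cause of the other shifts was not tested, except that the dark area held the genes lost without it.

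Of the lists called apart, 4 of 6 higher and 2 of 5 lower stayed so under every alternative for ACO against NCO, 6 of 10 and 2 of 2 for ASO against ACO, and 8 of 10 and 3 of 4 for ASO against NCO; 12, 7 and 6 lists that were not called became so under some alternative. For ACO against NCO these were CA3 cells, apoptosis, dentate granule cells, both microglia lists, ependyma, glucocorticoid targets, leptomeninges, oligodendrocyte precursors, oxidative phosphorylation, ribosomal proteins and unfolded protein response. For ASO against ACO they were NRF2, PPAR targets, astrocytes, immediate early genes, leptomeninges, oxidative phosphorylation and unfolded protein response, and for ASO against NCO NRF2, PPAR targets, blood, dentate granule cells, ribosomal proteins and thalamus. The cause was not tested for the calls that were lost, as follows. ACO against NCO: endothelium with normexp on spot means (-0.068), stricter filter (-0.070), spatial correction (-0.032) and list mean (-0.077); thalamus with no filter (0.045) and mean over probes (0.093); CA1 cells with quantile (-0.088), loess (-0.092), normexp on spot means (-0.048), stricter filter (-0.11) and list mean (-0.080); cytokines with no filter (0.019) and the negative-control threshold (0.079); glutamate receptors with quantile (-0.040) and normexp on spot means (-0.063). ASO against ACO: blood with quantile (0.11) and no filter (0.11); reactive astrocytes with the stricter filter (0.10); oligodendrocyte precursors with the negative-control threshold (0.13) and, reversed, the stricter filter (-0.00054); ribosomal proteins with quantile (0.0061), loess (0.10), normexp on spot means (0.19), stricter filter (0.17) and without the dark area (0.17). ASO against NCO: leptomeninges with quantile (0.10), loess (0.12) and stricter filter (0.10); astrocytes with mean over probes (0.095); oligodendrocytes with quantile (-0.14), normexp on spot means (-0.10), no filter (-0.14) and list mean (-0.082).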

Other observations

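The tests of uneven signal, microglial number, blood, the dark area and choroid plexus tissue in this part were chosen after their results were seen, and so were the genes of this paragraph. On ASO against ACO, single members of lists that did not stand apart differed more than their lists. The metallothionein genes Mt1 and Mt2, which buffer zinc, were at 0.54 and 0.35, Acot1, an acyl-CoA thioesterase, at 0.62, the lipid droplet gene Plin2 at 0.37 and the mitochondrial carrier gene Ucp2 at 0.34. The chaperone gene Hspa8 was at 0.53, Gstm1, a glutathione transferase, at 0.45 and the sulfotransferase gene Sult1a1 at -0.61. Penk, which encodes an opioid peptide precursor, was at -0.48 and Vip at -0.28.

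Microglial, complement and interferon genes stood higher on ASO than on ACO in 4 lists, the lowest median being 0.35. The tables argue against uneven signal across the array as the whole cause, because the lowest of the 4 medians was 0.37 after each spot was corrected by the spots around it. More microglia with unchanged expression cannot be told apart from altered expression: 11 homeostatic genes outside the complement list had a median of 0.32 against 0.59 for disease-associated genes, a gap within their SD of 0.35. That SD is a spread over genes and not the error of a median, so it cannot settle the question. P2ry12, the 1 lower gene of the 14 homeostatic genes, was at -0.40. Blood left in the tissue cannot be excluded either, since 8 of 12 blood genes were measured with a median of 0.21 (0.11 with quantile normalization) and an SD of 0.45. The globin genes Hba-a1, Hba-a2, Hbb-bt, Hbb-bs and Hbb-b2 lay at 0.07, 0.23, 0.34, 0.41 and 0.93, while the neutrophil gene S100a9, the 1 lower gene of the 8, was at -0.68. An effect of the oil, or an event in 1 pool such as injury or infection of a few mice, may also account for the pattern, and neither was tested.

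Of the 9 genes at least 2-fold lower on ASO than on ACO, 7 had their spots in the dark area, which held 37 of 13570 genes (0.273%). Of the 7, 4 were still at least 2-fold lower after correction by the surrounding spots. These were Ccdc59 at -1.52, Degs1 at -1.28, Pdp1 at -1.20 and Fra10ac1 at -1.19. Sort1 at -0.96, Klc1 at -0.84 and Abcb9 at -0.84 fell short of 2-fold. The spots around Degs1 stood at 0.095, so the correction could not remove a loss of signal there. The correction therefore cannot decide whether an even loss of signal over the area was the whole cause. Fignl1, in the same area, was higher on ASO, at 1.12. Damage to single spots there is a candidate explanation for the 7 that was not tested separately, and other probes of Pdp1 and Sort1 reached -0.21 and 0.10. An effect of the oil would not gather genes by their place on the array, and it stays open and untested for Ppp2r2c and Sh3bgr, which lay elsewhere. After correction by the surrounding spots these 2 were at -1.31 and -1.29. Sh3bgr was also at least 1.5-fold higher on ACO than on NCO and was not at least 2-fold lower on ASO than on NCO, so a high ACO value is part of its difference.

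Choroid plexus genes stood higher on ACO than on NCO, with a list median of 0.37. Uneven signal across the array as the whole cause is argued against by the median after correction by the surrounding spots, which was again 0.37. Choroid plexus tissue taken with the hippocampus would be likely to raise the brightest members with the rest, and the median of the 3 brightest was 0.22, with Igfbp2 at 0.30, Enpp2 at 0.22 and Ttr at -0.46. That lies within the members' SD of 0.26 of the list median, so dissection cannot be told apart from a response of the plexus to a peptide injected into the ventricles, which was not tested. The hippocampal pools gave 17 of the 19 list genes well above background on both arrays, and no gene of the list belongs to another list.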
